A study of Mus musculus with 6 samples.

How the data were processed

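Gene expression was measured by RNA sequencing in 6 libraries from mouse kidneys collected after bilateral ischemia and reperfusion. Of these, 3 came from animals given saline and 3 from animals given (+)CePPy. Per the labels' protocols, RNA was extracted with TRIzol, and libraries were made from 2 µg of total RNA with a Yeasen Hieff NGS dual-mode mRNA kit. Groups and replicate numbers were taken from the sample titles in the labels. The values used were whole-number read counts per gene deposited by the authors in 1 table for all samples, with no normalization, and the column names were matched to the samples through the labels. The submitters' processing notes name TopHat2, Cufflinks and DESeq without versions and the genome build GRCm38. The counting program, its handling of strand and of reads that map to several places, the annotation release and any filters are not given in the sources used here. Reads of near-identical genes could therefore be split between copies, and, if strand was not used, reads of overlapping genes on opposite strands would be mixed.

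The deposited table held 25031 genes, of which 22036 carried Ensembl identifiers. Of these, 22022 were found in the GENCODE M21 annotation of GRCm38, 21984 of them under the same symbol, and coordinates were taken from that annotation. The other 2995 entries, named NewGene and a number, are provisional loci from the authors' annotation without coordinates, and 945 of them were among the genes tested. A count of 0 in all libraries was found for 4988 genes, and 19 symbols occurred more than once. Total counts per library ranged from 29762157 to 37415213, and between 17413 and 17738 genes were detected in a library. NewGene loci took between 0.579% and 0.901% of counts and hemoglobin genes between 0.026% and 0.041%. Within each group, every pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom between 19.7 and 106 over genes with at least 20 counts in the pair, so none was counted as a copy of another.

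Low-count genes were removed with the filterByExpr function of edgeR 4.0.16 (R 4.3.3), which left 15416 genes, and libraries were scaled by the TMM method with factors between 0.95 and 1.03. The groups were compared with the quasi-likelihood test of edgeR on the counts, with treatment as the only term and 4 residual degrees of freedom. The common biological coefficient of variation was 0.186. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Log2 fold changes are CePPy against vehicle, levels are CPM on TMM-scaled library sizes, and errors are SD over 3 libraries or the SE of the fold change.

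Gene lists were compared with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 40 lists. Camera with an estimated correlation called 0 of the 40 lists, the lowest adjusted p being 0.549. The fry rotation test of limma called 0 with its genes moving, on balance, one way, and 20 with genes changing in either direction. For each list, edgeR p-values were also adjusted over the list alone. The lists covered kidney cell types (proximal tubule, thick ascending limb, distal convoluted and connecting tubule, collecting duct, podocyte, endothelium, fibroblast and extracellular matrix, smooth muscle and urothelium), tubular injury, blood cells, and adipose and adrenal tissue. Immune lists were macrophage and monocyte, neutrophil, T and NK cell, B and plasma cell, dendritic cell and antigen presentation, inflammatory cytokines and chemokines, interferon response, and complement and coagulation. Stress lists were NRF2 targets, antioxidant enzymes, superoxide and peroxide producers, ferroptosis and iron, unfolded protein and integrated stress response, heat shock, hypoxia, metallothionein and metal handling, scavenger receptors and lysosome, cell death, p53 targets, and stress and glucocorticoid response. The others were oxidative phosphorylation, mitochondrially encoded genes, fatty acid oxidation, glycolysis, cholesterol synthesis, cell cycle, immediate early genes, circadian clock, and androgen responsive and sex related kidney genes.

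The comparison, its test, the gene lists, the rule for naming genes and the alternatives were chosen before the data were examined. The rule named the genes with the largest change among those that passed with a mean of at least 2 CPM and no overlap between groups, leaving out provisional gene models. It also named 14 genes fixed in advance whatever their result, from Havcr1 to Cxcl1, and up to 4 members of each list described, taken by lowest p. With no gene passing in a direction, it took the 5 genes with the lowest p and said that none passed. The limits on CPM, overlap and names were kept for these 5. NewGene loci were not among the provisional names written into the rule. They were treated as provisional after the data were seen, because they have no coordinates or names, so the rule's last part was used in both directions.

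Alternatives were other scalings (the size factors of DESeq2, upper quartile, library totals), no filter or a stricter filter (at least 1 CPM in 3 libraries and 60 counts in total), DESeq2 1.42.0, limma-voom with and without sample weights, the replicate number as a term, and each library left out in turn. The procedure was tested on simulated counts with the means and sizes of these libraries, in 5 runs over 15218 to 15245 genes with 200 changed. For this comparison, edgeR recovered 33% of genes changed by 1.5-fold, 68.6% of those changed by 2-fold and 93.9% of those changed by 4-fold, and 3.9% of its calls were false. Camera called 0 of 200 unchanged simulated lists and 5 of 5 lists of 25 genes shifted by 1.4-fold. Simulated genes varied independently, which real genes of a list do not. Their variability followed the fitted trend with abundance, without the further scatter from gene to gene that real counts have. The shares recovered may therefore be too high for the real genes, and the number of real calls cannot be read against them. Transcript length and GC content, taken from the longest annotated transcript of each gene, were available for 14468 of the genes tested (93.9%).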

Results

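Messenger RNA was profiled by sequencing in kidneys of wild-type male C57BL/6 mice, a common inbred laboratory strain, aged 7 to 8 weeks. Every animal had both kidneys made ischemic for 23 minutes and then reperfused, a standard model of acute kidney injury, with body temperature held at 37 °C. The study set 3 kidney libraries from animals given saline (vehicle) against 3 from animals given 5 mg/kg of (+)CePPy. These are positively charged polypyrrole nanoparticles doped with cerium, given by vein straight after the injury. The time between injury and collection is not given in the sources used here, and no uninjured kidneys were analysed here. Total counts per library were 35114355, 33039101 and 34518294 for vehicle and 37415213, 37029050 and 29762157 for CePPy, and 1 count equalled between 0.0267 and 0.0336 CPM, the count scaled to the size of the library. Of 25031 genes counted, 15416 passed the filter on low counts and were tested.

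The comparison of CePPy with vehicle asks how the nanoparticles changed transcript levels in the injured kidney. Marker genes of the proximal tubule, thick ascending limb, distal tubule and collecting duct were higher after CePPy, with median log2 fold changes of 0.70, 0.73, 0.36 and 0.46. Tubular injury markers, with a median of -0.49, and neutrophil genes, with a median of -1.09, were lower. Targets of NRF2, the transcription factor that switches on genes against oxidative stress, were lower too, with a median of -0.49. The interferon and the T and NK cell lists were called higher too, by less than the spread between the vehicle libraries. These shifts were called for whole gene lists, while only 1 single gene passed the edgeR test over all genes. All 18 list calls were lost when the correlation between the genes of a list was estimated from these libraries (lowest camera adjusted p = 0.549).

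The libraries separated by treatment along the first principal component of log2 CPM, which held 38.5% of the variance. Vehicle libraries lay at -29.8, -18.1 and -28.7 and CePPy libraries at 56.8, 3.8 and 16.0, so CePPy 1 stood farthest out and CePPy 2 nearest to vehicle. Correlations of log2 CPM, taken across genes, were 0.9797 to 0.9822 between vehicle libraries, 0.971 to 0.9793 between CePPy libraries and 0.9584 to 0.9823 across the groups. Mitochondrial transcripts took 12.7%, 11.8% and 14.8% of counts in vehicle and 14.99%, 14.3% and 14.8% in CePPy. The labels do not say that each library came from a separate animal, so the p-values measure the spread between these libraries, which may be technical. An exact permutation test of 3 against 3 samples cannot give a two-sided p below 0.1.

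At the level of single genes, edgeR called 0 genes higher and 1 lower at an adjusted p under 0.05. An unadjusted p under 0.05 was reached by 2931 genes, 1487 higher and 1444 lower, where chance gives 771. The gene that fell was NewGene_5251, a provisional locus from the authors' own annotation with no coordinates in the sources used here. It went from 93.5 ± 3.56 to 34.8 ± 4.71 CPM (SD, n = 3 per group), a log2 fold change of -1.43 (SE 0.11, edgeR adjusted p = 0.015), and was named after its values were seen. The CePPy and vehicle values did not overlap for 4048 genes (26.3%), where chance gives 10%. The count depended on the tool: DESeq2 called 993 genes (512 higher, 481 lower), limma-voom with sample weights 352, limma-voom 1 and edgeR without the filter on low counts 63. It also depended on single libraries, as edgeR called 811 genes without CePPy 2, 6 without vehicle 2, 2 without CePPy 1 and 0 without vehicle 1, vehicle 3 or CePPy 3.

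The 5 annotated genes with the lowest p in each direction did not pass, each with an edgeR adjusted p of 0.0739. They were taken from genes with a mean of at least 2 CPM and no overlap between groups, so their separation was set by the selection. Among those with higher values was Slc5a1, the sodium-glucose cotransporter SGLT1 of the late proximal tubule (chromosome 5, 33104219 to 33162870, plus strand, GRCm38). It measured 65.5 ± 5.12 CPM in vehicle and 115 ± 9.82 in CePPy, a log2 fold change of 0.81 (SE 0.10). Cldn19, a tight junction claudin of the thick ascending limb needed for magnesium reabsorption (chromosome 4, 119255414 to 119262438, plus strand), measured 18.2 ± 3.44 and 40.1 ± 5.52 CPM (log2 fold change 1.14, SE 0.16). The epithelial chemokine gene Ccl28 (chromosome 13, 119623819 to 119654359, plus strand) measured 1.53 ± 0.569 and 7.92 ± 2.11 CPM (2.36, SE 0.32). Abi3bp, which encodes an extracellular matrix protein (chromosome 16, 56477878 to 56690135, plus strand), measured 5.76 ± 0.623 and 13.5 ± 1.19 CPM (1.23, SE 0.14). Serpina1c, an alpha-1-antitrypsin gene (chromosome 12, 103894926 to 103904887, minus strand), measured 3.85 ± 0.516 and 11.5 ± 2.98 CPM (1.58, SE 0.22), and its reads may be shared with near-identical neighbours.

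The genes with lower values included Gadd45g, a growth arrest and stress gene (chromosome 13, 51846678 to 51848468, plus strand), at 54.8 ± 7.09 CPM in vehicle and 26.8 ± 3.52 in CePPy (log2 fold change -1.03, SE 0.13). Fbp2, a fructose-1,6-bisphosphatase of gluconeogenesis (chromosome 13, 62836877 to 62858422, minus strand), measured 52.2 ± 8.30 and 25.1 ± 1.09 CPM (-1.05, SE 0.12). Hist1h1c, a linker histone gene (chromosome 13, 23738808 to 23740367, plus strand), measured 142 ± 13.2 and 75.7 ± 8.68 CPM (-0.91, SE 0.11). Slc25a48, a carrier of the inner mitochondrial membrane (chromosome 13, 56438355 to 56474239, plus strand), measured 45.0 ± 0.268 and 27.1 ± 2.13 CPM (-0.73, SE 0.09). Nhp2, a protein of the complex that modifies ribosomal RNA (chromosome 11, 51619735 to 51623714, plus strand), measured 90.4 ± 5.62 and 56.5 ± 4.29 CPM (-0.68, SE 0.09).

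Marker lists of all 4 tubule segments examined were higher in CePPy kidneys. Of 38 proximal tubule genes, 36 had higher values, and the list rose by camera (adjusted p = 4.96e-09; adjusted p = 0.718 with an estimated correlation). With edgeR, 19 members were higher adjusted over the list alone and 0 over all genes, and DESeq2 called 14 of them higher over all genes. Slc7a9, part of the cystine and basic amino acid transporter, measured 53.3 ± 3.01 CPM in vehicle and 80.9 ± 11.1 in CePPy (log2 fold change 0.60, SE 0.11). The water channel gene Aqp1 measured 261 ± 36.7 and 571 ± 234 CPM (1.13, SE 0.27) and the organic anion transporter gene Slc22a8 131 ± 4.38 and 263 ± 93.4 (1.01, SE 0.24). Ttc36 measured 48.2 ± 5.02 and 147 ± 89.8 (1.61, SE 0.39). All 4 had an edgeR adjusted p of 0.0196 over the list alone. Slc34a1, the main renal phosphate cotransporter, was higher in each CePPy library but did not pass over all genes, at 1095 ± 62.1 and 2597 ± 1263 CPM (1.25, SE 0.31, edgeR adjusted p = 0.121). Lrp2, the endocytic receptor megalin, measured 614 ± 30.8 and 912 ± 378 CPM (0.57, SE 0.26, edgeR adjusted p = 0.288).

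The thick ascending limb list rose as well, with 10 of 11 genes at higher values (camera adjusted p = 2.32e-05; adjusted p = 0.59 with an estimated correlation). By edgeR, 9 members were higher adjusted over the list alone and 0 over all genes, and DESeq2 called 8. Egf, the growth factor made by this segment and the distal tubule, measured 18.1 ± 0.582 CPM in vehicle and 158 ± 149 in CePPy (log2 fold change 3.12, SE 0.67), with CePPy libraries at 324, 37.9 and 111 CPM. Ptger3, a prostaglandin E2 receptor gene, measured 11.7 ± 1.64 and 20.4 ± 4.30 CPM (0.81, SE 0.18), and Tmem72 29.7 ± 2.36 and 49.4 ± 12.0 (0.73, SE 0.17). In the distal convoluted and connecting tubule list all 13 genes had higher values (camera adjusted p = 0.000769; adjusted p = 0.718 with an estimated correlation). Of these, 5 were higher by edgeR adjusted over the list alone, 0 over all genes, and 3 by DESeq2. The calcium-binding parvalbumin gene Pvalb measured 0.176 ± 0.136 and 3.56 ± 3.60 CPM (4.32, SE 1.10), with CePPy libraries at 7.43, 0.319 and 2.93 CPM and vehicle 2, at 0.324 CPM, above CePPy 2. Tmem52b measured 101 ± 8.42 and 171 ± 51.7 (0.75, SE 0.20). Smaller differences were seen for the ion channel gene Trpm7, at 77.7 ± 6.04 and 96.6 ± 5.63 CPM (0.31, SE 0.09). The same held for Trpv5, the calcium channel of this segment, at 18.4 ± 1.70 and 23.6 ± 1.11 CPM (0.36, SE 0.10).

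All 18 collecting duct genes had higher values (camera adjusted p = 5.66e-06; adjusted p = 0.549 with an estimated correlation). Of these, 8 were higher by edgeR adjusted over the list alone, 0 over all genes, and 4 by DESeq2. The water channel gene Aqp2 measured 122 ± 26.3 CPM in vehicle and 212 ± 46.3 in CePPy (log2 fold change 0.80, SE 0.20). Avpr2, the vasopressin receptor gene that controls it, measured 2.71 ± 0.684 and 6.10 ± 1.62 (1.17, SE 0.27). The bicarbonate exchangers of intercalated cells, Slc4a9 at 18.8 ± 0.698 and 26.8 ± 3.05 CPM (0.51, SE 0.11) and Slc4a1 at 8.38 ± 2.81 and 17.2 ± 6.47 (1.04, SE 0.31), went the same way. The mean level of the proximal tubule list against vehicle was 1.13, 0.15 and 0.69 log2 units in CePPy 1, 2 and 3, and that of the collecting duct list 0.56, 0.37 and 0.61. Genes of podocytes and endothelium did not move as lists, with medians of -0.05 over 14 genes (camera adjusted p = 0.585) and 0.04 over 18 genes (camera adjusted p = 0.494). These podocyte and endothelium tests gave an adjusted p above 0.05 and do not show that the genes were equal. With a library left out, the podocyte median ranged from -0.10 (without vehicle 2) to 0.01 (without CePPy 3).

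**Figure D1:**
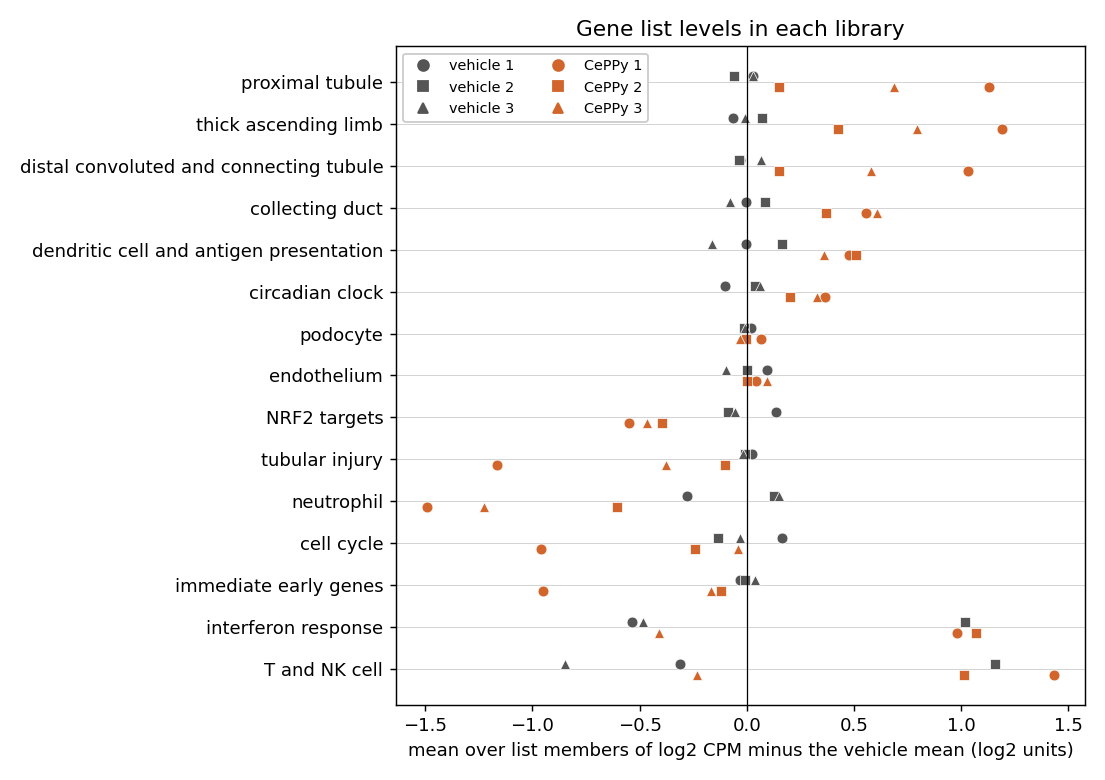
Mean level of 15 gene lists in each library, as log2 CPM minus the vehicle mean averaged over the list's members (log2 units); each point is 1 library, vehicle in grey and CePPy in orange, with the replicate given by the symbol. CePPy 1 lies farthest from vehicle for the proximal tubule (1.13) and tubular injury (-1.16) lists, and the interferon list is high in vehicle 2, CePPy 1 and CePPy 2 alike.

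Markers of tubular injury fell as a list, with 24 of 28 genes at lower values (camera adjusted p = 1.89e-05; adjusted p = 0.718 with an estimated correlation). With edgeR, 5 members were lower adjusted over the list alone and 0 over all genes, and DESeq2 called 6 lower. Lgals3, the galectin-3 gene, measured 310 ± 44.8 CPM in vehicle and 184 ± 20.2 in CePPy (log2 fold change -0.75, SE 0.13). Sox9, a transcription factor switched on in repairing tubule cells, measured 30.9 ± 1.404 and 14.1 ± 5.43 CPM (-1.13, SE 0.26). Plaur, the urokinase receptor gene, measured 58.3 ± 2.44 and 39.5 ± 8.65 (-0.56, SE 0.15). Cdkn1a, the cell cycle inhibitor p21, measured 67.6 ± 5.06 and 42.0 ± 8.21 CPM (-0.69, SE 0.14). The injury marker genes Havcr1 (KIM-1), Lcn2 (NGAL) and Krt20 had lower values in each CePPy library without passing the edgeR test. Havcr1 measured 2917 ± 55.4 and 1707 ± 673 CPM (-0.77, SE 0.25, edgeR adjusted p = 0.168). Lcn2 measured 442 ± 69.2 and 267 ± 152 CPM (-0.73, SE 0.44, edgeR adjusted p = 0.395). Krt20 measured 204 ± 11.9 and 124 ± 64.6 (-0.73, SE 0.38, edgeR adjusted p = 0.339). The list level was -1.16, -0.10 and -0.38 in CePPy 1, 2 and 3, and the median of -0.49 became -0.29 without CePPy 1 and -0.73 without CePPy 2.

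NRF2 targets were lower after CePPy at a similar level in its 3 libraries, whose list levels were -0.55, -0.40 and -0.47 log2 units. Of 32 genes, 25 had lower values (camera adjusted p = 5.28e-08; adjusted p = 0.549 with an estimated correlation). By edgeR, 20 members were lower and 2 higher (Osgin1 and Gstm3, named after their values were seen) adjusted over the list alone, 0 over all genes, and DESeq2 called 18 lower. Gsta4, a glutathione transferase that clears lipid peroxidation products, measured 90.8 ± 24.4 CPM in vehicle and 31.8 ± 5.11 in CePPy (log2 fold change -1.51, SE 0.21, edgeR adjusted p over the list alone = 0.00168). Gsta1, another transferase whose reads may be shared with Gsta2, measured 88.3 ± 13.5 and 26.5 ± 10.7 CPM (-1.74, SE 0.28). Gsr, the glutathione reductase gene, measured 312 ± 23.0 and 197 ± 12.9 CPM (-0.66, SE 0.09). Taldo1, of the pentose phosphate pathway, measured 424 ± 1.47 and 288 ± 23.5 (-0.56, SE 0.09). Hmox1, heme oxygenase 1, measured 330 ± 47.9 and 161 ± 33.7 CPM (-1.03, SE 0.17, edgeR adjusted p = 0.0813 over all genes). Nqo1, a quinone reductase, measured 109 ± 19.0 and 63.1 ± 11.3 (-0.79, SE 0.16, edgeR adjusted p = 0.102). Gclc, the catalytic subunit of glutathione synthesis, went the other way, at 364 ± 22.4 and 406 ± 21.3 CPM (0.16, SE 0.09, edgeR adjusted p = 0.366).

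Other genes of oxidant defence did not move together. The list of 30 antioxidant enzymes did not pass (camera adjusted p = 0.81), and its test pointed down while its median of 0.03 and mean of 0.04 lay above 0. Within it, DESeq2 called 1 gene higher and 3 lower over all genes. By edgeR, 1 gene was lower adjusted over the list alone: Txn1, the cytosolic thioredoxin, at 493 ± 9.34 CPM in vehicle and 376 ± 18.9 in CePPy (log2 fold change -0.39, SE 0.08). The peroxiredoxin gene Prdx6 measured 386 ± 19.4 and 296 ± 34.1 CPM (-0.38, SE 0.11). The mitochondrial thioredoxin reductase gene Txnrd2 measured 27.7 ± 1.47 and 22.4 ± 1.08 (-0.30, SE 0.09) and Gpx6, of the glutathione peroxidase family, 6.76 ± 1.03 and 18.2 ± 11.0 (1.43, SE 0.40). Sod2, the mitochondrial superoxide dismutase, measured 190 ± 3.68 and 225 ± 46.8 CPM (0.24, SE 0.14, edgeR adjusted p = 0.395). Cat, catalase, measured 694 ± 76.5 and 791 ± 120 (0.19, SE 0.14, edgeR adjusted p = 0.494). The 15 genes for producers of superoxide and peroxide did not pass either (camera adjusted p = 0.976), with a test that pointed down, a median of 0.12 and a mean of 0.01. Cybb, the phagocyte oxidase subunit, measured 11.3 ± 2.07 and 12.5 ± 0.928 CPM (0.14, SE 0.15, edgeR adjusted p = 0.652).

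The ferroptosis and iron list, which shares Hmox1, Slc7a11, Ftl1 and Fth1 with the NRF2 list, did not pass (median -0.07 over 25 genes, camera adjusted p = 0.0548). It passed without vehicle 1, vehicle 2, CePPy 1 or CePPy 3, with a camera adjusted p between 0.0339 and 0.0475, and its median was -0.14 without CePPy 3. By edgeR, 3 members were lower adjusted over the list alone, 0 over all genes, and DESeq2 called 4 lower. Slc7a11, the cystine importer that feeds glutathione synthesis, measured 3.43 ± 0.0547 CPM in vehicle and 1.39 ± 0.196 in CePPy (log2 fold change -1.30, SE 0.23, edgeR adjusted p over the list alone = 0.0064). The ferritin genes Ftl1, at 4711 ± 581 and 2964 ± 231 CPM (-0.67, SE 0.13), and Fth1, at 9624 ± 708 and 7147 ± 205 (-0.43, SE 0.13), were also lower. Each ferritin gene has processed copies in the genome that could share its reads. Over the list alone, edgeR gave Ftl1 an adjusted p of 0.00962 and Fth1 0.0595.

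Neutrophil genes showed the largest median of the lists that fell, with 12 of 13 at lower values (median -1.09, camera adjusted p = 1.89e-05; adjusted p = 0.59 with an estimated correlation). By edgeR, 8 were lower adjusted over the list alone, 0 over all genes, and DESeq2 called 5 lower. The calprotectin genes S100a8, at 10.1 ± 2.02 CPM in vehicle and 2.89 ± 0.978 in CePPy (log2 fold change -1.81, SE 0.28), and S100a9, at 19.0 ± 4.31 and 5.95 ± 2.38 (-1.67, SE 0.31), were lower. So were the gelatinase gene Mmp9, at 6.79 ± 0.254 and 3.04 ± 0.760 CPM (-1.16, SE 0.22), and Csf3r, the receptor for the granulocyte growth factor, at 9.11 ± 1.87 and 4.40 ± 1.67 (-1.05, SE 0.29). The macrophage and monocyte list did not pass (median -0.08 over 24 genes, camera adjusted p = 0.229). By edgeR, 0 members passed adjusted over the list alone, 1 was higher and 2 lower at an unadjusted p under 0.05, and DESeq2 called 1 lower. Single libraries moved the macrophage list: without vehicle 3 it passed (median -0.19, camera adjusted p = 0.0441), and without vehicle 2 its median was -0.01 (camera adjusted p = 0.695). Its member with the lowest p was Chil3, a chitinase-like gene of activated macrophages, at 12.0 ± 2.93 and 4.47 ± 2.23 CPM (-1.42, SE 0.36). Aif1 measured 2.09 ± 0.206 and 3.29 ± 0.455 CPM (0.66, SE 0.23) and Tyrobp 13.4 ± 0.777 and 10.6 ± 1.30 (-0.35, SE 0.13). Lyz2, lysozyme, measured 80.9 ± 13.5 and 62.4 ± 12.9 (-0.37, SE 0.17).

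The 35 inflammatory cytokine and chemokine genes did not pass as a list (median -0.15, camera adjusted p = 0.178), and edgeR called 1 higher and 2 lower adjusted over the list alone. Without CePPy 2 the list passed (median -0.33, camera adjusted p = 0.0121). Its median was -0.02 without vehicle 2, -0.04 without CePPy 1, -0.26 without vehicle 1 and -0.24 without vehicle 3, with a camera adjusted p between 0.0626 and 0.668. Il1b, interleukin 1 beta, fell within the list from 16.3 ± 1.30 to 5.10 ± 1.93 CPM (log2 fold change -1.68, SE 0.27, edgeR adjusted p over the list alone = 0.00872). Nfkbia, the inhibitor of NF-kappaB and itself an NF-kappaB target, fell from 65.8 ± 14.1 to 37.2 ± 6.99 CPM (-0.82, SE 0.19, edgeR adjusted p over the list alone = 0.027). Cxcl9, a chemokine induced by interferon gamma, rose from 1.03 ± 0.103 to 3.25 ± 1.16 CPM (1.65, SE 0.32, edgeR adjusted p over the list alone = 0.0169). Il11 measured 7.50 ± 0.819 and 3.82 ± 1.76 CPM (-0.97, SE 0.33, edgeR adjusted p over the list alone = 0.143). The cytokine gene Il6 measured 1.602 ± 0.303 and 0.941 ± 0.410 CPM (-0.76, SE 0.39, edgeR adjusted p over all genes = 0.327). Ccl2, which recruits monocytes, measured 14.5 ± 2.50 and 9.06 ± 2.76 CPM (-0.68, SE 0.23, edgeR adjusted p = 0.188). Cxcl1, which recruits neutrophils, measured 60.2 ± 21.02 and 29.6 ± 13.4 (-1.02, SE 0.38, edgeR adjusted p = 0.205).

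Genes of antigen presentation rose, with 14 of 15 at higher values (median 0.50, camera adjusted p = 0.00051; adjusted p = 0.549 with an estimated correlation). Of these, 5 were higher by edgeR adjusted over the list alone, 0 over all genes, and 5 by DESeq2. The class II genes H2-Eb1, at 42.0 ± 6.68 CPM in vehicle and 65.8 ± 13.3 in CePPy (log2 fold change 0.65, SE 0.17), and H2-Ab1, at 58.1 ± 13.4 and 102 ± 28.4 (0.81, SE 0.23), were among them. So were H2-Aa, at 41.7 ± 9.54 and 61.9 ± 8.31 CPM (0.57, SE 0.17), and Cd74, the invariant chain, at 126 ± 31.5 and 193 ± 24.7 CPM (0.61, SE 0.18). For each of these genes vehicle 2 was the highest vehicle library and CePPy 3 the lowest CePPy library, as for the interferon list. In vehicle 2 and CePPy 3, H2-Eb1 stood at 49.5 and 50.8 CPM and H2-Ab1 at 73.3 and 73.1, which overlapped. H2-Aa stood at 51.3 and 53.9 CPM in these libraries and Cd74 at 162 and 173. The list level was -0.002, 0.16 and -0.16 log2 units in vehicle 1, 2 and 3 and 0.48, 0.51 and 0.36 in CePPy 1, 2 and 3. Reads of the H2 genes may be shared within that family.

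The interferon response list was called higher, with 33 of 34 genes at higher values (median 0.45, camera adjusted p = 0.00582; adjusted p = 0.799 with an estimated correlation). The call rested on how single libraries fell: the list level was -0.53, 1.02 and -0.49 log2 units in vehicle 1, 2 and 3 and 0.98, 1.07 and -0.41 in CePPy 1, 2 and 3. Its camera adjusted p became 0.188 without vehicle 1, 0.158 without vehicle 3, 0.174 without CePPy 1 and 0.303 without CePPy 2, with medians of 0.22, 0.23, 0.30 and 0.21. The median was 1.21 without vehicle 2 and 0.79 without CePPy 3. With edgeR, 0 members passed over the list alone or over all genes, 1 had an unadjusted p under 0.05, and 0 passed with DESeq2. Gbp2, an interferon-induced GTPase gene, had the lowest p, at 30.05 ± 10.9 CPM in vehicle and 47.7 ± 13.4 in CePPy (log2 fold change 0.67, SE 0.28). Igtp measured 29.4 ± 13.1 and 54.4 ± 26.3 CPM (0.89, SE 0.42), Gbp3 24.6 ± 15.2 and 41.3 ± 20.5 (0.75, SE 0.50) and Mx1 1.53 ± 1.02 and 2.71 ± 1.38 (0.83, SE 0.57).

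The T and NK cell list followed the same libraries, at -0.31, 1.16 and -0.85 log2 units in vehicle 1, 2 and 3 and 1.44, 1.01 and -0.23 in CePPy 1, 2 and 3. All 18 genes had higher means in CePPy (median 0.58, camera adjusted p = 0.0214; adjusted p = 0.759 with an estimated correlation). However, 0 passed by edgeR over the list alone or over all genes, 1 had an unadjusted p under 0.05, and 0 passed by DESeq2. The camera adjusted p became 0.115 without vehicle 1, 0.356 without vehicle 3, 0.259 without CePPy 1 and 0.206 without CePPy 2. The median was 0.28 without CePPy 1, 1.52 without vehicle 2 and 1.05 without CePPy 3. The lymphocyte receptor genes Cd4, at 1.03 ± 0.208 and 2.10 ± 0.822 CPM (log2 fold change 1.03, SE 0.38), and Cd6, at 0.408 ± 0.361 and 1.03 ± 0.642 (1.34, SE 0.76), had the lowest p. They were followed by Cd2, at 0.311 ± 0.266 and 0.706 ± 0.391 (1.18, SE 0.69), and Klrb1c, at 0.292 ± 0.0939 and 0.582 ± 0.392 (1.01, SE 0.64).

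Cell cycle genes fell, with 44 of 45 at lower values (median -0.38, camera adjusted p = 5.78e-07; adjusted p = 0.718 with an estimated correlation). With edgeR, 0 members passed over the list alone or over all genes, 12 were lower at an unadjusted p under 0.05, and DESeq2 called 6 lower. Cdt1, which licenses replication origins, measured 43.9 ± 3.96 CPM in vehicle and 25.6 ± 6.58 in CePPy (log2 fold change -0.78, SE 0.18). The replication helicase genes Mcm6, at 126 ± 8.52 and 87.4 ± 16.5 CPM (-0.53, SE 0.14), and Mcm2, at 86.7 ± 2.42 and 58.8 ± 13.3 (-0.56, SE 0.15), had lower values. The mitotic kinase gene Aurka measured 6.23 ± 1.51 and 3.78 ± 0.316 CPM (-0.72, SE 0.22). The list level was 0.17, -0.14 and -0.03 in vehicle 1, 2 and 3 and -0.96, -0.24 and -0.04 in CePPy 1, 2 and 3. CePPy 3 thus lay within the vehicle range, and the median was -0.15 without CePPy 1 (camera adjusted p = 0.00113).

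Immediate early genes, which respond to growth factors and stress within minutes, fell too, with 23 of 28 at lower values (median -0.33, camera adjusted p = 0.000319; adjusted p = 0.718 with an estimated correlation). By edgeR, 4 were lower adjusted over the list alone, 0 over all genes, and DESeq2 called 6 lower. These 4 were Klf2, Nr4a1, Dusp5 and Zfp36. Klf2 measured 34.3 ± 5.52 CPM in vehicle and 21.8 ± 2.25 in CePPy (log2 fold change -0.66, SE 0.14) and the nuclear receptor gene Nr4a1 18.8 ± 4.90 and 8.79 ± 2.49 (-1.10, SE 0.25). Dusp5, a phosphatase gene, measured 22.6 ± 3.35 and 11.8 ± 3.30 CPM (-0.93, SE 0.22) and Zfp36, which destabilises cytokine messages, 178 ± 34.4 and 79.9 ± 34.0 (-1.15, SE 0.32). Without CePPy 1 the median was -0.15 (camera adjusted p = 0.00726), and the list level in that library was -0.95 against -0.12 and -0.17 in CePPy 2 and 3.

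Targets of p53, the transcription factor of the DNA damage response, fell, with 20 of 25 at lower values (median -0.17, camera adjusted p = 0.0157; adjusted p = 0.59 with an estimated correlation). Besides Cdkn1a, edgeR called Aen, Bax and Gdf15 lower adjusted over the list alone, 0 members over all genes, and DESeq2 called 4. Aen, a nuclease gene of apoptosis, measured 53.8 ± 2.86 CPM in vehicle and 39.8 ± 4.10 in CePPy (log2 fold change -0.44, SE 0.10). The cell death gene Bax measured 69.6 ± 6.03 and 46.7 ± 8.35 (-0.58, SE 0.14) and Gdf15, a secreted stress factor, 77.2 ± 20.2 and 38.2 ± 14.3 (-1.01, SE 0.28). The median was -0.27 without CePPy 2. The stress and glucocorticoid list fell with 10 of 14 genes lower (median -0.46, camera adjusted p = 0.0214; adjusted p = 0.718 with an estimated correlation). Of these, 4 were lower by edgeR adjusted over the list alone, 0 over all genes, and 4 by DESeq2. The metallothionein genes Mt1, at 365 ± 20.6 and 195 ± 45.1 CPM (-0.90, SE 0.17), and Mt2, at 310 ± 13.8 and 156 ± 58.6 (-0.99, SE 0.26), were lower. Ddit4, an inhibitor of mTORC1 signalling, measured 59.3 ± 11.9 and 29.0 ± 9.28 CPM (-1.03, SE 0.25). Glucocorticoid receptor targets lay on both sides. The 4 members with higher values, named after their values were seen, were Tsc22d3 (log2 fold change 0.40, SE 0.16, edgeR adjusted p = 0.227), Zbtb16 (0.99, SE 0.50), Klf9 (0.15, SE 0.14) and Fkbp5 (0.13, SE 0.11), and 0 of the 4 passed by edgeR over the list alone, 1 having an unadjusted p under 0.05. Among the members with lower values were Sgk1 (-0.26, SE 0.15) and Per1 (-0.23, SE 0.21), also named after their values were seen. Without vehicle 3, the camera adjusted p of the stress list became 0.102.

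Clock genes rose, with 13 of 17 at higher values (median 0.28, camera adjusted p = 0.0011; adjusted p = 0.549 with an estimated correlation). Of these, 7 were higher by edgeR adjusted over the list alone, 0 over all genes, and 6 by DESeq2. Per2, a core clock repressor, measured 17.3 ± 1.96 CPM in vehicle and 34.3 ± 5.32 in CePPy (log2 fold change 0.98, SE 0.14, edgeR adjusted p over the list alone = 0.00191). Per3 measured 11.5 ± 0.667 and 17.9 ± 1.19 CPM (0.64, SE 0.11) and the repressor Cry1 5.90 ± 0.450 and 10.5 ± 1.81 (0.83, SE 0.17). Hlf, a transcription factor driven by the clock, measured 34.7 ± 1.47 and 67.2 ± 17.2 (0.95, SE 0.18). The list did not move one way throughout. The members with lower values, named after their values were seen, were Npas2 (-0.82, SE 0.31), Arntl (-0.27, SE 0.21), Per1 (-0.23, SE 0.21) and Bhlhe40 (-0.23, SE 0.16). Of these, Npas2 had the lowest edgeR adjusted p over the list alone, at 0.0657. The hour of collection is not given in the sources used here. The list level was 0.37, 0.20 and 0.33 in CePPy 1, 2 and 3, and the median was 0.43 without vehicle 3.

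Cholesterol synthesis genes were called higher, with 19 of 20 at higher means (median 0.41, camera adjusted p = 0.000233, or 0.718 with an estimated correlation). However, edgeR called 0 over the list alone or over all genes, against 8 at an unadjusted p under 0.05 and 4 called by DESeq2. Hmgcs1, the synthase ahead of the rate-limiting step, measured 313 ± 56.0 CPM in vehicle and 508 ± 119 in CePPy (log2 fold change 0.70, SE 0.19). The later enzymes Cyp51, at 63.9 ± 16.1 and 111 ± 37.8 CPM (0.80, SE 0.26), and Idi1, at 52.7 ± 14.3 and 84.4 ± 20.2 (0.68, SE 0.22), also had higher values. Nsdhl measured 56.0 ± 5.04 and 76.3 ± 16.5 CPM (0.45, SE 0.15). The median was 0.26 both without vehicle 1 and without CePPy 1. The list level was -0.29, 0.27 and 0.02 in vehicle 1, 2 and 3 and 0.68, 0.44 and 0.06 in CePPy 1, 2 and 3. The groups overlapped, with vehicle 2 above CePPy 3. The highest levels were in CePPy 1, CePPy 2 and vehicle 2, where the interferon list was also high.

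All 13 mitochondrially encoded messages had higher means in CePPy (median 0.24, camera adjusted p = 0.00481, or 0.731 with an estimated correlation). Of these, 0 passed the edgeR test over the list alone or over all genes, 1 had an unadjusted p under 0.05, and 0 passed by DESeq2. The complex I subunit genes mt-Nd4l, at 1006 ± 190 CPM in vehicle and 1308 ± 62.8 in CePPy (log2 fold change 0.38, SE 0.14), and mt-Nd4, at 11049 ± 1574 and 13576 ± 874 (0.30, SE 0.15), had the lowest p. They were followed by mt-Nd6, at 3868 ± 642 and 4623 ± 192 CPM (0.26, SE 0.14), and mt-Nd5, at 10968 ± 1839 and 13250 ± 652 (0.27, SE 0.16). The camera adjusted p was 0.114 without vehicle 2 (median 0.15) and 0.0536 without CePPy 1, and the median was 0.37 without vehicle 3. The list level was -0.09, -0.165 and 0.26 in vehicle 1, 2 and 3 and 0.33, 0.14 and 0.19 in CePPy 1, 2 and 3. Vehicle 3 thus lay above CePPy 2 and CePPy 3. The oxidative phosphorylation genes of the nucleus were called higher by a small amount, with 55 of 64 at higher values (median 0.13, camera adjusted p = 0.0136; adjusted p = 0.87 with an estimated correlation). Of these, 0 passed by edgeR over the list alone or over all genes, 1 had an unadjusted p under 0.05, and 0 passed by DESeq2. The complex II genes Sdha, at 501 ± 28.9 and 629 ± 106 CPM (0.33, SE 0.13), and Sdhb, at 181 ± 7.02 and 225 ± 49.0 (0.32, SE 0.15), had the lowest p. They were followed by Ndufs1 of complex I, at 188 ± 14.7 and 230 ± 45.5 CPM (0.29, SE 0.14), and Uqcrc2 of complex III, at 348 ± 5.87 and 411 ± 63.9 (0.24, SE 0.12). This call depended on CePPy 1, without which the median was -0.01 (camera adjusted p = 0.244). It was also lost without vehicle 1 (camera adjusted p = 0.0661) and without vehicle 2 (0.0792), and the median was 0.23 without CePPy 2.

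**Figure D2:**
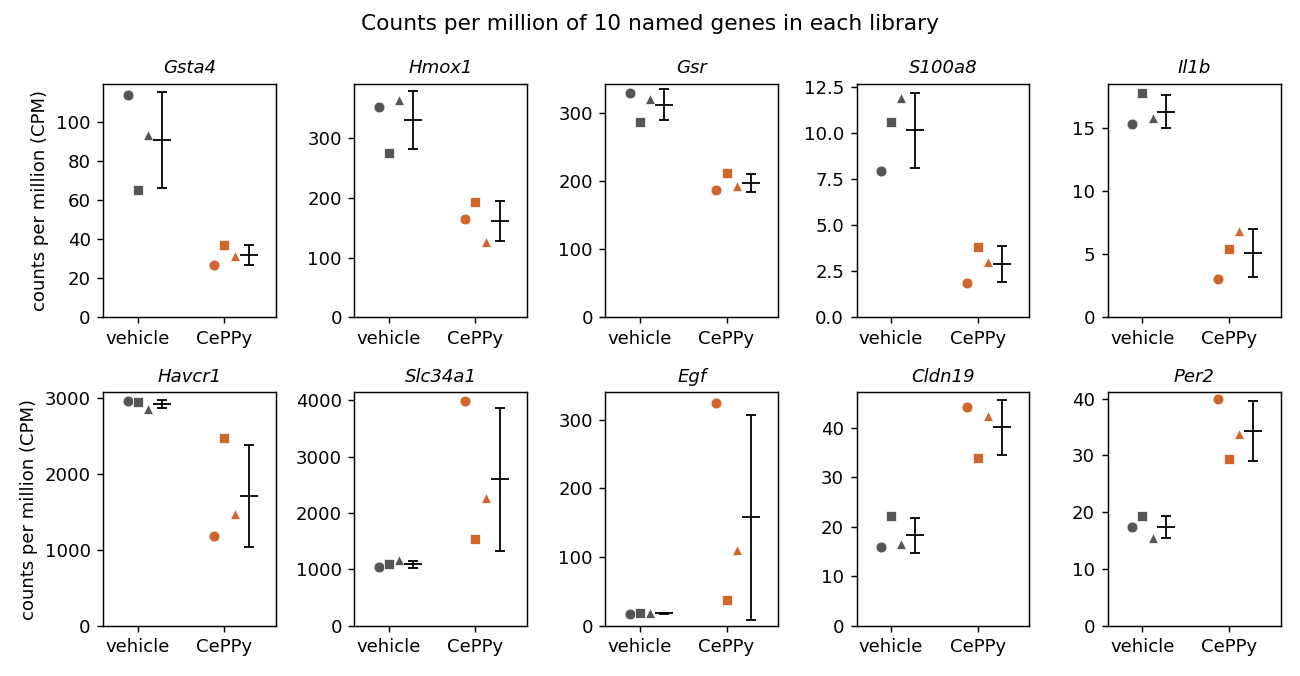
Level of 10 genes in each library (CPM, each gene on its own linear axis from 0), with vehicle in grey and CePPy in orange; points are libraries and bars give the mean ± SD of 3 libraries. Gsta4, Hmox1, Gsr, S100a8, Il1b and Havcr1 have lower values in all 3 CePPy libraries, and Slc34a1, Egf, Cldn19 and Per2 higher values, with an edgeR adjusted p between 0.0739 and 0.168 over all genes.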

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

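The alternatives were chosen before the data were examined, and no test in this part was chosen after the result was seen. Against 1 gene called by edgeR, other scalings, the stricter filter and limma-voom also called 1 gene, NewGene_5251 in each. No filter gave 63 genes (35 of them at least 2-fold), DESeq2 993 (227) and limma-voom with sample weights 352 (83), where CePPy 1 had a weight of 0.38 and CePPy 3 of 1.80; beyond the different tools and filters, the cause was not tested. Leaving out single libraries gave 0 to 811 genes and 0 to 270 at least 2-fold, with 2000 to 3761 at an unadjusted p under 0.05 by edgeR and the highest counts without CePPy 2. NewGene_5251 lost its call without vehicle 1 (edgeR adjusted p = 0.179), vehicle 3 (0.205) and CePPy 3 (0.192). With the replicate number as a term (replicate block), edgeR called 0 genes and 0 at least 2-fold (2632 had an unadjusted p under 0.05), NewGene_5251 having an adjusted p of 0.0968, and camera 18 lists. Libraries that shared a number did not deviate together (r across genes -0.15, 0.098 and -0.021, where vehicle 1 and CePPy 3 gave 0.18), so the numbers are not taken as pairs. Of 1916 results for named genes under an alternative, 0 changed direction, 1667 kept their side of the threshold, 245 newly passed and 4 no longer passed. The first component held 35% of the variance over the 500 most variable genes, in the same order of groups.

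Against 18 lists called by camera, the size factors of DESeq2 gave 18, no filter 19, single libraries left out 16 to 20, and the estimated correlation and fry 0 and 0; both of these allow for genes of a list that vary together. Of 440 list results, 352 kept direction and side, 49 no longer passed, 13 newly passed and 26 changed the direction of the test; the cause was not tested. Of the called lists, the calls of 5 (interferon, T and NK cell, oxidative phosphorylation, mitochondrially encoded, stress) were lost without a single library, as given with each, and the median of oxidative phosphorylation ranged from -0.008 to 0.232. The other lists that changed direction were not called. With a library left out, their medians ranged from 0 to 0.066 (endothelium), -0.001 to 0.186 (fibroblast), -0.049 to 0.083 (antioxidant), -0.01 to 0.16 (superoxide), -0.019 to 0.202 (fatty acid oxidation), -0.072 to 0.029 (glycolysis), 0.03 to 0.21 (metallothionein), -0.185 to 0.069 (blood) and -0.235 to 1.39 (smooth muscle and urothelium). Other settings that turned their test gave medians of 0.093 (fibroblast, fry), 0.131 (superoxide, no filter), 0.137, 0.141 and 0.115 (metallothionein; fry, size factors of DESeq2, no filter) and -0.064 (blood, no filter). Ferroptosis and iron newly passed without the filter (camera adjusted p = 0.0442) and without vehicle 1 (0.0411), vehicle 2 (0.0339), CePPy 1 (0.0475) or CePPy 3 (0.047). The other lists that newly passed did so without a single library, as given with each. Scaling moved the median over all genes to between -0.023 and 0.01. At this depth, where 1 count equals 0.0267 to 0.0336 CPM, Pvalb in vehicle 1, at 0.0557 CPM, rests on few counts.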

Other observations

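The gene families below, and the tests of the patterns and of the count of genes at an unadjusted p, were chosen after the result was seen, as were the genes named for them, apart from the test of Nfe2l2 and the splits of the libraries for the called genes and lists. The unfolded protein and integrated stress response list of 26 genes did not pass (median 0.16, mean 0.03, camera adjusted p = 0.177; median 0.26 and adjusted p = 0.0835 without CePPy 3) and held members that differed in both directions. With edgeR adjusted over the list alone, 12 members were higher, among them the chaperone genes Dnajc3, at 144 ± 4.46 CPM in vehicle and 205 ± 18.1 in CePPy (log2 fold change 0.51, SE 0.09), and Sdf2l1, at 15.7 ± 1.05 and 26.0 ± 5.77 (0.73, SE 0.16). The 4 that were lower included the serine synthesis genes Phgdh, at 68.9 ± 8.28 and 42.4 ± 8.00 CPM (-0.70, SE 0.15), and Psat1, at 111 ± 4.90 and 79.8 ± 9.57 (-0.48, SE 0.10). The list of androgen responsive and sex related kidney genes did not pass either (median 0.62 over 13 genes, camera adjusted p = 0.0879). It did pass without CePPy 2 (0.78, camera adjusted p = 0.022), and its median was 0.38 without CePPy 1. It held 7 members higher and 2 lower by edgeR adjusted over the list alone. Cyp2e1 went from 113 ± 17.3 to 555 ± 326 CPM (2.30, SE 0.38) and the transporter gene Slc22a30 from 35.8 ± 3.52 to 80.4 ± 39.9 (1.17, SE 0.32). The male-typical fatty acid hydroxylases went down, Cyp4a12a from 112 ± 7.11 to 74.7 ± 3.82 CPM (-0.59, SE 0.08) and its close paralog Cyp4a12b from 159 ± 8.56 to 81.9 ± 24.3 (-0.96, SE 0.19).

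Complement and coagulation genes (median 0.07 over 26, camera adjusted p = 0.333; median 0.16 without vehicle 1, 0.14 without vehicle 2, 0.17 without CePPy 1 and 0.15 without CePPy 3) held 4 higher and 2 lower by edgeR adjusted over the list alone. Coagulation factor F5 went from 2.40 ± 0.622 to 6.30 ± 1.02 CPM (log2 fold change 1.39, SE 0.24), complement factor Cfb from 263 ± 37.2 to 401 ± 62.8 (0.61, SE 0.14), and the complement inhibitor Serping1 from 59.97 ± 11.5 to 89.7 ± 8.20 (0.58, SE 0.15). Thbd, the endothelial anticoagulant thrombomodulin, went from 68.3 ± 3.42 to 49.1 ± 1.93 CPM (-0.48, SE 0.08). Hypoxia genes (median 0.06 over 23, camera adjusted p = 0.349; median 0.15 without vehicle 1, 0.10 without CePPy 2 and 0.01 without CePPy 3) held 3 higher and 2 lower. The vasodilator gene Adm went from 16.1 ± 0.979 to 7.94 ± 1.09 CPM (-1.02, SE 0.14), the glycolysis regulator Pfkfb3 from 16.5 ± 0.446 to 28.6 ± 4.06 (0.79, SE 0.12), and Ak4, a mitochondrial adenylate kinase, from 94.0 ± 9.77 to 241 ± 127 (1.36, SE 0.35). Fatty acid oxidation genes (median 0.09 over 35, camera adjusted p = 0.645) held 2 higher and 2 lower, and passed without CePPy 2 (0.20, camera adjusted p = 0.0219) but had a median of -0.02 without vehicle 2 or CePPy 1 and 0.01 without CePPy 3. The thioesterase genes Acot1, from 89.9 ± 28.3 to 29.6 ± 2.46 CPM (-1.60, SE 0.21), and its paralog Acot2, from 43.2 ± 11.2 to 20.6 ± 1.84 (-1.07, SE 0.18), went down. Cyp4a14, a PPAR alpha target, went from 205 ± 52.1 to 381 ± 65.4 CPM (0.89, SE 0.20) and Ppargc1a, a regulator of mitochondrial number, from 27.1 ± 3.58 to 39.8 ± 6.46 (0.56, SE 0.15). The remaining lists did not pass by camera: adipose and adrenal (median 0.76, adjusted p = 0.0969), cell death (-0.09, adjusted p = 0.1), scavenger receptors and lysosome (-0.06, adjusted p = 0.231), B and plasma cell (0.25, adjusted p = 0.327), heat shock (0.01, adjusted p = 0.43) and smooth muscle and urothelium (0.85, adjusted p = 0.585). Single libraries moved the medians of all 6 by over 1.5 times, and 3 passed without one. Adipose and adrenal passed without vehicle 1 (1.398, camera adjusted p = 0.0388) and without CePPy 1 (1.38, camera adjusted p = 0.00269). Cell death passed without CePPy 2 (-0.14, camera adjusted p = 0.0146), and B and plasma cell without vehicle 2 (1.02, camera adjusted p = 0.0197). The adipose median was 0.49 without CePPy 3, and that of cell death -0.055 and -0.056 without CePPy 1 and CePPy 3. The B and plasma cell median was 0.51 without vehicle 1, 0.12 without vehicle 3 and 0.52 without CePPy 3. Smooth muscle and urothelium ranged from -0.235 (without CePPy 3) to 1.39 (without vehicle 1), heat shock from -0.03 (without vehicle 1) to 0.08 (without vehicle 2), and scavenger receptors and lysosome from -0.05 (without vehicle 1) to -0.11 (without CePPy 1). Within the heat shock list, Hspa1b went from 59.1 ± 4.27 to 108 ± 25.9 CPM (log2 fold change 0.88, SE 0.16). Its edgeR adjusted p was 0.0115 over the list alone and 0.0884 over all genes. Chordc1, Hspa1a and Hsph1 were also higher by edgeR over the list alone (adjusted p = 0.0475 each). DESeq2 called 4 heat shock genes higher and 0 lower. In 4 more lists the camera test pointed up while the median or the mean lay below 0: blood cells (median -0.04, mean 0.13, adjusted p = 0.764), glycolysis (median -0.01, mean 0.06, adjusted p = 0.925), fibroblast and extracellular matrix (median 0.09, mean -0.02, adjusted p = 0.951) and metallothionein and metal handling (median 0.14, mean -0.10, adjusted p = 0.999).

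Of 12 gene families formed after the data were seen, camera called 7, and 0 with an estimated correlation, where the lowest adjusted p was 0.409. Ribosomal protein genes were lower in 79 of 82 cases (median log2 fold change -0.39, camera adjusted p = 3.83e-33), and 75 were lower by edgeR adjusted over the family alone. Their share of all counts was 2.81% to 3.20% in vehicle and 2.11% to 2.47% in CePPy, and their mean level -0.37, -0.29 and -0.46 in CePPy 1, 2 and 3. Rplp1, a stalk protein of the large subunit, went from 539.8 ± 26.0 to 367.3 ± 15.6 CPM. Proteasome subunit genes were lower in 35 of 39 cases (median -0.17, camera adjusted p = 3.09e-07), mitochondrial ribosomal proteins in 67 of 78 (-0.11, camera adjusted p = 2.84e-05) and tubulins in 9 of 12 (-0.30, camera adjusted p = 0.0331). The groups overlapped for tubulins, at 0.12, -0.04 and -0.08 in vehicle 1, 2 and 3 and -0.30, 0.01 and -0.12 in CePPy 1, 2 and 3. Mitochondrial ribosomal proteins stood at -0.03 in both vehicle 1 and CePPy 1. Higher were the H2 genes (0.42, camera adjusted p = 7.3e-05), the serpin clade A of protease inhibitors (1.01, camera adjusted p = 0.000616) and the UDP-glucuronosyltransferases (0.73, camera adjusted p = 0.00107). The H2 level was 0.31 in vehicle 2, above the 0.11 of CePPy 3, and highest in CePPy 1 (0.75) and CePPy 2 (0.51), the libraries in which the interferon list was also high. The UDP-glucuronosyltransferase level was 0.21 in vehicle 3, above the 0.16 of CePPy 2. Of the 7 called families, fry called the ribosomal proteins (adjusted p = 0.0271) and serpin clade A (0.0389) but not the proteasome (0.0532), mitochondrial ribosomal proteins (0.127), H2 genes (0.13), UDP-glucuronosyltransferases (0.0819) or tubulins (0.13). Cytochromes P450 did not pass (0.34, camera adjusted p = 0.0528), and collagens, organic anion transporters, glutathione transferases and retinol dehydrogenases had a camera adjusted p of 0.123, 0.123, 0.187 and 0.324.

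Ribosomal protein genes are short and abundant, so their lower level was set against technical explanations. Other genes matched on length and GC content of the longest annotated transcript had a median of -0.06 over 367 genes (quartiles -0.24 and 0.19). This argues against an effect of that transcript's length or GC. The transcript expressed may be shorter, so an effect of its length is not settled. Genes matched on mean CPM had a median of -0.03 over 349 genes (quartiles -0.16 and 0.18), which argues against the scaling of abundant genes. The family median was between -0.39 and -0.42 under the scalings tried and between -0.34 and -0.44 with a library left out. The median of 4 ribosomal pseudogenes, those with a ribosomal protein symbol ending in -ps, was -0.46, all lower. Copies under other names were not looked for, and these 4 are too few to settle whether reads moved between copies. A difference in ribosome production with treatment may also explain the pattern, as a hypothesis that was not tested.

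The rise of all 4 tubule segment lists was weighed in the same way. Podocyte and endothelium genes, pooled, had a median of -0.01 over 32 genes (quartiles -0.10 and 0.13), which argues against a smaller share of these resident cells in the CePPy samples. Without CePPy 1, 4 of the 4 lists still rose by camera, with medians of 0.47 (proximal tubule), 0.55 (thick ascending limb), 0.27 (distal tubule) and 0.33 (collecting duct). Camera also called 8 to 21 lists in splits of the libraries not made by treatment, so these calls alone cannot decide. The levels of all 4 lists in CePPy 2 and CePPy 3 lay above every vehicle library, which argues against CePPy 1 alone. The distal list came closest, at 0.15 in CePPy 2 and 0.07 in vehicle 3. The samples may differ in how much tubule gene expression was kept or regained after CePPy, but also in the depth of injury or the part of kidney taken, and neither was tested.

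NRF2 targets were lower after particles that are given against oxidative stress, per the labels. The list still fell without CePPy 1 (median -0.45, camera adjusted p = 1.03e-07, range of medians with a library left out -0.45 to -0.56). Its level was -0.40 and -0.47 in CePPy 2 and 3 and no lower than -0.085 in a vehicle library, which argues against CePPy 1 alone. Nfe2l2, the NRF2 gene, had a log2 fold change of -0.10 (SE 0.10, 155.8 ± 8.39 and 145.8 ± 15.2 CPM, edgeR adjusted p = 0.626), which argues against a drop in its transcript, and Keap1, the gene of its inhibitor, had -0.02 (SE 0.08, edgeR adjusted p = 0.935). Bach1, a repressor of some of the same targets, had 0.26 (SE 0.10, edgeR adjusted p = 0.226), with an unadjusted p under 0.05, and a part for it stays open. List levels ranged over 0.15 in the CePPy libraries while injury levels ranged over 1.06, but 3 libraries are too few to separate lower oxidative signalling from milder injury, and these cannot be told apart.

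The 6 libraries can be split into 3 and 3 in 10 ways, so the share of splits is never under 0.1, too few for a share under 0.05. For called genes, 5 splits gave as many as the real one, which gave 1, and the highest other gave 50. For genes at least 2-fold changed, 5 splits gave as many, with 1 in the real split and 41 in the highest other. For called lists, 4 splits gave as many, with 18 in the real one and 21 in the highest other. For genes with an unadjusted p under 0.05, 1 split, the real one, reached 2931, and the highest other gave 901. The split that called 50 genes set vehicle 2, CePPy 1 and CePPy 2 against the others, which points to a structure of the samples apart from treatment. All 50 were higher in those 3 libraries, 27 of them in the interferon response list and 2, Gzma and Gzmb, in the T and NK cell list. By edgeR, Irf7, a regulator of interferon genes, differed by 2.50 on the log2 scale (adjusted p = 0.000222) and Isg15 by 2.17 (adjusted p = 0.00128), and the cause was not tested.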
